A study of Homo sapiens with 30 samples.

How the data were processed

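RNA sequencing of 30 human neuroblastoma libraries was compared, in 10 groups of 3. Both lines carry MYCN amplification per the series title. SK-N-BE(2)-C cells, called BE2C here, and Kelly cells were each sequenced as naive or JQ1-resistant cells after 24 h in vehicle or JQ1, an inhibitor of BET bromodomain proteins. A further pair of groups held BE2C cells engineered to express GFP or PI3K. The series design calls the 3 libraries of each group biological replicates. Whether they are separate cultures or separate derivations of the resistant or engineered cells is not stated. The p-values below measure spread between libraries and cannot be read as spread between derivations. The labels give neither the JQ1 dose, nor how the resistant cells were derived, nor which PI3K gene was expressed. They also do not say whether resistant cells were kept in JQ1 until the 24 h in vehicle.

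The values are read counts per gene symbol, 1 file per library, as the authors deposited them. Per the labels, the libraries were strand-specific mRNA libraries read from 1 end at 75 bp on a NextSeq500. The submitters' processing notes name FastQC, TopHat2 (version 2), featureCounts and the builds GRCh37 and hg19, with no role or settings. Whether reads were counted by strand is not stated. Each file held 25728 gene entries. Of these, 28 carried names that a spreadsheet had turned into dates and were left out, which left 25700. The reference at hand was of another build than those named, so no coordinates are given.

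Library totals ranged from 24.1 to 68.3 M counts. A lower bound on a fold against a group with no counts was computed from a floor of 3 counts over that group. Such floors cover counting error only. There were no spike-in controls, so every change is relative to the composition of the library.

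Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. The 12 drug-experiment libraries of each line were fitted together, with 4 groups, and the 6 GFP and PI3K libraries apart. Genes were kept by edgeR's filterByExpr, libraries were scaled by TMM factors, and contrasts were tested by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over the genes tested. The threshold was an adjusted p under 0.05. Log2 fold changes are those of the edgeR fit with its default prior count and are given ± SE. The SE was back-calculated as the absolute log2 fold change divided by the square root of the F statistic. For large changes against a group with few counts it can lie below the counting error. A prior count of 2 was used only for the log CPM of the principal components and of the replicate-number correlations. Group levels are TMM-scaled CPM ± SD over 3 libraries. There were 11 comparisons. In each line these were JQ1 against vehicle in naive cells and in resistant cells, resistant against naive cells in vehicle and in JQ1, and the interaction, which is the JQ1 response of resistant cells minus that of naive cells. The last comparison was PI3K against GFP. The replicate numbers were not treated as pairs. In the drug experiments libraries of the same number had lower median correlations (-0.0622 in BE2C, -0.0329 in Kelly) than libraries of different numbers (0.0260 and 0.0217). In the PI3K experiment the 3 same-number pairs had 0.0255 against -0.0142.

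The lists of genes, the comparisons and the rule for naming genes were fixed before the data were examined. The 27 lists covered BET inhibitor marker genes, BET proteins and P-TEFb, adrenergic core circuitry, mesenchymal state, catecholamine and secretory granule, neuronal differentiation, MYC family targets, G1/S and G2/M cell cycle, CDK inhibitors and cyclins, BCL2 family, receptor tyrosine kinases, PI3K pathway components, FOXO targets, sterol and fatty acid synthesis, ATF4 amino acid response, ERK feedback, Wnt targets, hypoxia and glycolysis, interferon response, p53 targets and drug efflux. Markers of Schwann and neural crest cells, fibroblasts, epithelial cells and blood and endothelial cells, and mitochondrially encoded genes, made up the rest. Lists with at least 5 tested members were compared with all other genes by camera on the edgeR fit, two-sided, with a preset correlation of 0.01 and adjustment over the lists of a comparison. Each was tested again with the correlation estimated from its members. Between experiments that share no libraries, the 200 strongest rises and the 200 strongest falls of 1 comparison, ranked by F statistic, were tested as lists in the other.

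Named genes were, for every comparison, MYCN, MYC, HEXIM1, BCL2, CDKN1A and PIK3CA, with PIK3CB, PIK3CD, PIK3CG and PIK3R1 added for PI3K against GFP. To these were added the 10 largest rises and 10 largest falls with an adjusted p under 0.05, a mean of at least 5 CPM in the higher group and no overlap between the groups, a separation that chance gives in 10% of 3 against 3 comparisons. Genes without a proper symbol could be left out. For the interaction, a mean of at least 5 CPM in 1 group was asked. For each list described, up to 4 members with the smallest adjusted p were eligible. Some genes that the rule names are not reported here.

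The test was checked on simulated data with the depth and spread of each comparison and 200 changed genes. Of genes changed by 1 on the log2 scale, 79.6% to 95.9% were recovered, and of those changed by 0.5, 29.9% to 80.0%. False calls numbered at most 18 per comparison. Alternatives were RLE factors, total counts, DESeq2 1.42.0, no filter on low counts, a stricter filter of 10 CPM in 3 libraries, a minimum log2 change of 1, a fit of the 2 groups alone, a replicate block, and each replicate left out in turn. For lists they were the estimated correlation and fry. For lists taken from another experiment they were the top 100 genes and all called genes.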

Results

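Messenger RNA was sequenced in 30 libraries of MYCN-amplified neuroblastoma cells, in 10 groups of 3. Naive and JQ1-resistant cells of the BE2C and Kelly lines were each measured after 24 h in vehicle or in JQ1, which displaces BET bromodomain proteins from acetylated chromatin. The other pair of groups compared BE2C cells expressing PI3K, a lipid kinase that activates AKT, with cells expressing GFP. Library totals were 32.6 to 32.9 M counts in naive BE2C vehicle cells and 24.1 to 29.1 M in naive BE2C cells in JQ1. In resistant BE2C cells they were 31.0 to 40.6 M in vehicle and 31.9 to 33.5 M in JQ1. Kelly libraries held 33.4 to 52.0 M (naive vehicle), 33.7 to 46.5 M (naive JQ1), 39.0 to 42.7 M (resistant vehicle) and 28.7 to 35.8 M (resistant JQ1). GFP libraries held 61.3 to 65.7 M counts and PI3K libraries 46.6 to 68.3 M. The 10 most abundant genes took 3.88% to 5.53% of the counts as group means. In the principal component analyses the first component separated resistant from naive BE2C libraries with 63.5% of the variance, and PI3K from GFP libraries with 81.4%. In Kelly it carried 62.7% and also separated resistant from naive libraries, with JQ1 libraries further toward the resistant side in both states. Levels below are CPM ± SD (n = 3) and changes are log2 fold changes ± SE.

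**Figure D1:**
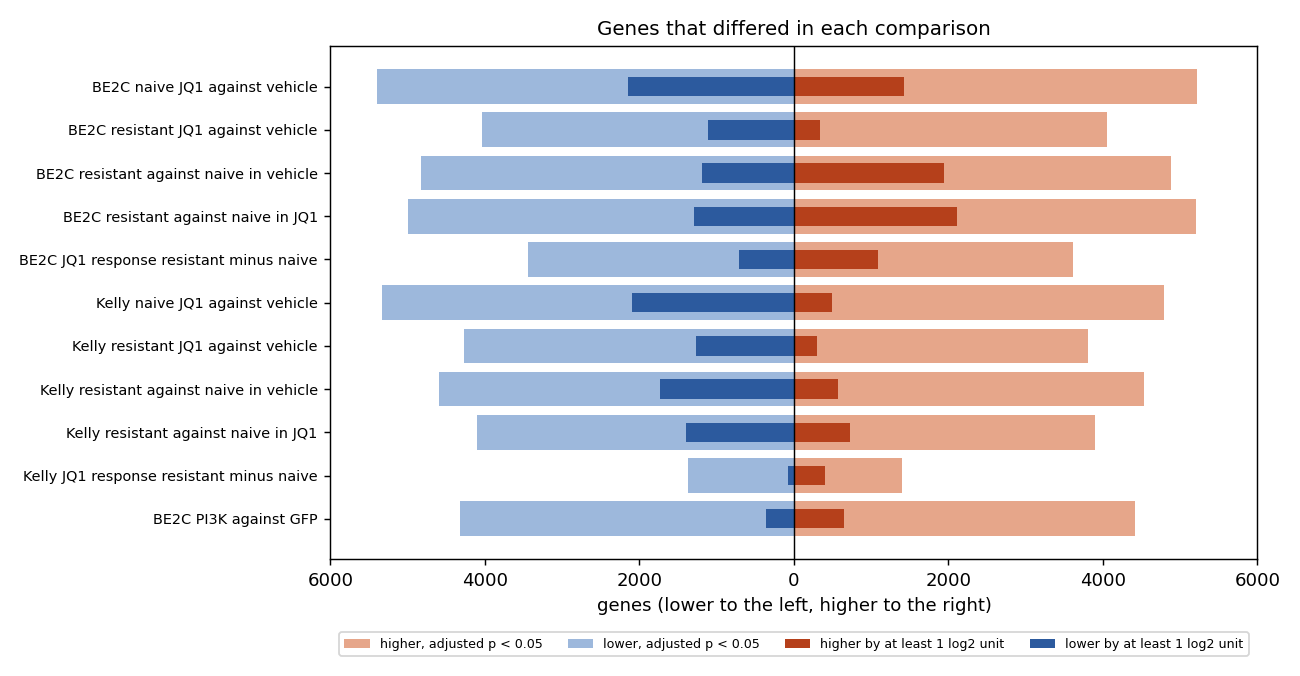
Number of genes called higher (right) or lower (left) in each of the 11 comparisons; pale bars count an adjusted p under 0.05 and dark bars those that also changed by at least 1 on the log2 scale. Naive BE2C cells had 5213 genes higher and 5396 lower in JQ1, and the Kelly interaction had the fewest, 1395 higher and 1370 lower.

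JQ1 in naive BE2C cells addressed the response of sensitive cells to BET inhibition. Histone genes and HEXIM1, an inhibitor of the elongation factor P-TEFb, rose, while MYCN, its target genes and DNA replication genes fell. HIST2H2BE rose by 4.99 ± 0.07, from 10.01 ± 0.366 to 319 ± 2.05 CPM, and HEXIM1 rose by 2.92 ± 0.06, from 36.5 ± 0.123 to 276 ± 10.9 CPM. MYCN, the amplified oncogene, was 2765 ± 128 CPM in vehicle and 1059 ± 9.24 CPM in JQ1, a change of -1.38 ± 0.05 (adjusted p = 2.89e-12). BCL2, which blocks apoptosis, changed by -2.07 ± 0.11. CDKN1A, the p21 inhibitor of cyclin-dependent kinases, rose by 1.12 ± 0.14, to 4.30 CPM. PIK3CA rose by 0.39 ± 0.09. MYC stayed under 1 CPM in both groups.

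All 12 tested BET inhibitor marker genes rose (12 adjusted over the list alone), with a median of 4.12, among them HIST1H2AC (5.04 ± 0.10) and HIST1H2BD (4.24 ± 0.08). All 28 G1/S genes fell (28 adjusted over the list alone), with a median of -1.10. The DNA replication factor MCM10 and the phosphatase CDC25A changed by -1.69 ± 0.06 and -1.75 ± 0.06. Of 35 MYC family targets, 32 fell, 2 rose and 1 did not pass (33 fell and 2 rose adjusted over the list alone), including the nucleolar genes NOP16 (-1.73 ± 0.06) and DKC1 (-1.21 ± 0.05). Of 27 G2/M genes, 22 fell, 1 rose and 4 did not pass (23 and 1 adjusted over the list alone). Of 28 sterol and fatty acid synthesis genes, 21 fell, 1 rose and 6 did not pass (22 and 1 adjusted over the list alone). Wnt targets fell in 10 of 13 cases with none higher (10 adjusted over the list alone), including the secreted inhibitor DKK1, which went from 60.6 to 1.56 CPM (-5.29 ± 0.14). FOXO targets, known to rise when AKT signalling is low, rose in 17 of 23 cases and fell in 5 (17 and 5 adjusted over the list alone), among them TXNIP (1.99 ± 0.06) and CCNG2 (1.84 ± 0.08). Fibroblast markers, of which 11 were tested, fell in 9 cases and rose in 1 (9 and 1 adjusted over the list alone), with COL3A1, a collagen, at -2.32 ± 0.07. Camera placed these lists apart from other genes at adjusted p = 3.48e-38 for the BET markers, 3.06e-19 for G1/S, 1.91e-10 for MYC targets, 2.61e-06 for Wnt, 1.81e-05 for sterol, 5.52e-05 for FOXO and for fibroblast markers and 0.000139 for G2/M, and each call held with an estimated correlation. ERK feedback genes fell in 15 of 20 cases and rose in 3 (15 and 3 adjusted over the list alone; adjusted p = 0.00265), a call lost at adjusted p = 0.269 with an estimated correlation. BET proteins and P-TEFb rose in 6 of 10 cases with none lower (6 adjusted over the list alone; adjusted p = 0.0154, and adjusted p = 0.0939 with an estimated correlation), with BRD2 at 0.76 ± 0.07.

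Other genes of these naive cells moved far without a list-wide call. MLKL, the executor of necroptosis, and OAS1, an interferon-induced enzyme, fell, at -7.10 ± 0.25 and -6.999 ± 0.27. The granins CHGA and CHGB, proteins of secretory granules, rose (1.68 ± 0.08 and 1.89 ± 0.07), while DDC, the dopamine-forming decarboxylase, fell by 1.95 ± 0.06. The 19 tested catecholamine and secretory granule genes split, 9 higher and 7 lower (10 and 7 adjusted over the list alone), with a median of 0.14 and a mean of -0.33 (adjusted p = 0.908). Of 23 adrenergic core genes, 9 rose and 11 fell (10 and 11 adjusted over the list alone; adjusted p = 0.512), with TFAP2B at -1.75 ± 0.06. Of 15 BCL2 family genes, 5 rose and 8 fell (5 and 8 adjusted over the list alone; adjusted p = 0.769), among them the pro-apoptotic BMF (1.97 ± 0.09). Of 18 p53 targets, 9 rose and 6 fell (9 and 7 adjusted over the list alone; adjusted p = 0.161), with a median of 0.19 and a mean of -0.14. Of 6 Schwann and neural crest markers 5 fell (5 adjusted over the list alone; adjusted p = 0.161); the median was -2.07, or -1.29 with the member that had an empty group set at its bound. Of 7 epithelial markers 2 rose and 3 fell (2 and 3 adjusted over the list alone; adjusted p = 0.769). In all, edgeR's quasi-likelihood test called 5213 genes higher and 5396 lower of 14649.

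JQ1 in resistant BE2C cells and the interaction asked which parts of that response the resistant cells kept. MYCN rose slightly in resistant cells, from 957 ± 19.6 to 1233 ± 44.2 CPM (0.37 ± 0.05, adjusted p = 2.15e-05), so that its response differed from that of naive cells by 1.75 ± 0.07 (adjusted p = 4.15e-10). HEXIM1 and HIST2H2BE still rose, by 1.77 ± 0.06 and 2.03 ± 0.06, but less than in naive cells, with interactions of -1.15 ± 0.08 and -2.96 ± 0.09. BCL2 fell by 1.58 ± 0.11, and its interaction of 0.49 ± 0.15 (adjusted p = 0.0152) was lost without naive JQ1 replicate 3 (0.38) or resistant JQ1 replicate 2 (0.40). CDKN1A had an interaction of -0.82 ± 0.17 and PIK3CA one of -0.30 ± 0.12 (adjusted p = 0.0574). The largest falls in resistant cells included SLC18A1, a vesicular monoamine transporter, at -5.26 ± 0.16 and TRIM29 at -6.74 ± 0.22. The largest interactions were those of HDAC9, a histone deacetylase (3.92 ± 0.10), and ANGPT2, an angiopoietin (-4.003 ± 0.17).

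All 12 BET inhibitor marker genes again rose in resistant BE2C cells (12 adjusted over the list alone; median 1.87, adjusted p = 3.58e-22), and all 12 had a negative interaction (12 adjusted over the list alone; median -2.23, adjusted p = 3.22e-20). The G1/S list had 27 of 28 genes with a positive interaction and none negative (28 adjusted over the list alone; median 1.08, adjusted p = 3.73e-27), such as CDC6, a replication licensing factor (1.24 ± 0.07). MYC family targets had 33 of 35 positive and none negative (34 adjusted over the list alone; median 0.91, adjusted p = 3.22e-20), with NOP16 at 1.39 ± 0.09. In resistant cells themselves, 6 MYC targets rose and 10 fell (6 and 10 adjusted over the list alone; adjusted p = 0.942), and G1/S genes fell in 17 cases and rose in 4 (18 and 6 adjusted over the list alone; adjusted p = 0.0861). The G2/M, sterol and Wnt lists had 18, 16 and 9 positive interactions and 1, 2 and 1 negative (19, 16 and 10 against 1, 2 and 2 adjusted over the list alone), at adjusted p = 0.000680, 0.000114 and 0.000630. Each of these 6 interaction calls held with an estimated correlation. ATF4 amino acid response genes had 11 of 21 positive and 2 negative (12 and 2 adjusted over the list alone; adjusted p = 0.000319, and adjusted p = 0.102 with an estimated correlation), among them the serine synthesis gene PSAT1 (1.45 ± 0.07). Fibroblast markers fell in 10 of 11 cases in resistant cells (10 adjusted over the list alone; adjusted p = 9.70e-08, held with an estimated correlation), with COL6A3 at -3.63 ± 0.17. Catecholamine genes fell in 10 of 19 cases and rose in 8 (11 and 8 adjusted over the list alone; adjusted p = 0.000875, and adjusted p = 0.0804 with an estimated correlation), with DBH and TH, which make noradrenaline and DOPA, at -2.61 ± 0.08 and -2.24 ± 0.10. The test called 4051 genes higher and 4039 lower in resistant cells, and 3614 positive and 3437 negative interactions.

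**Figure D2:**
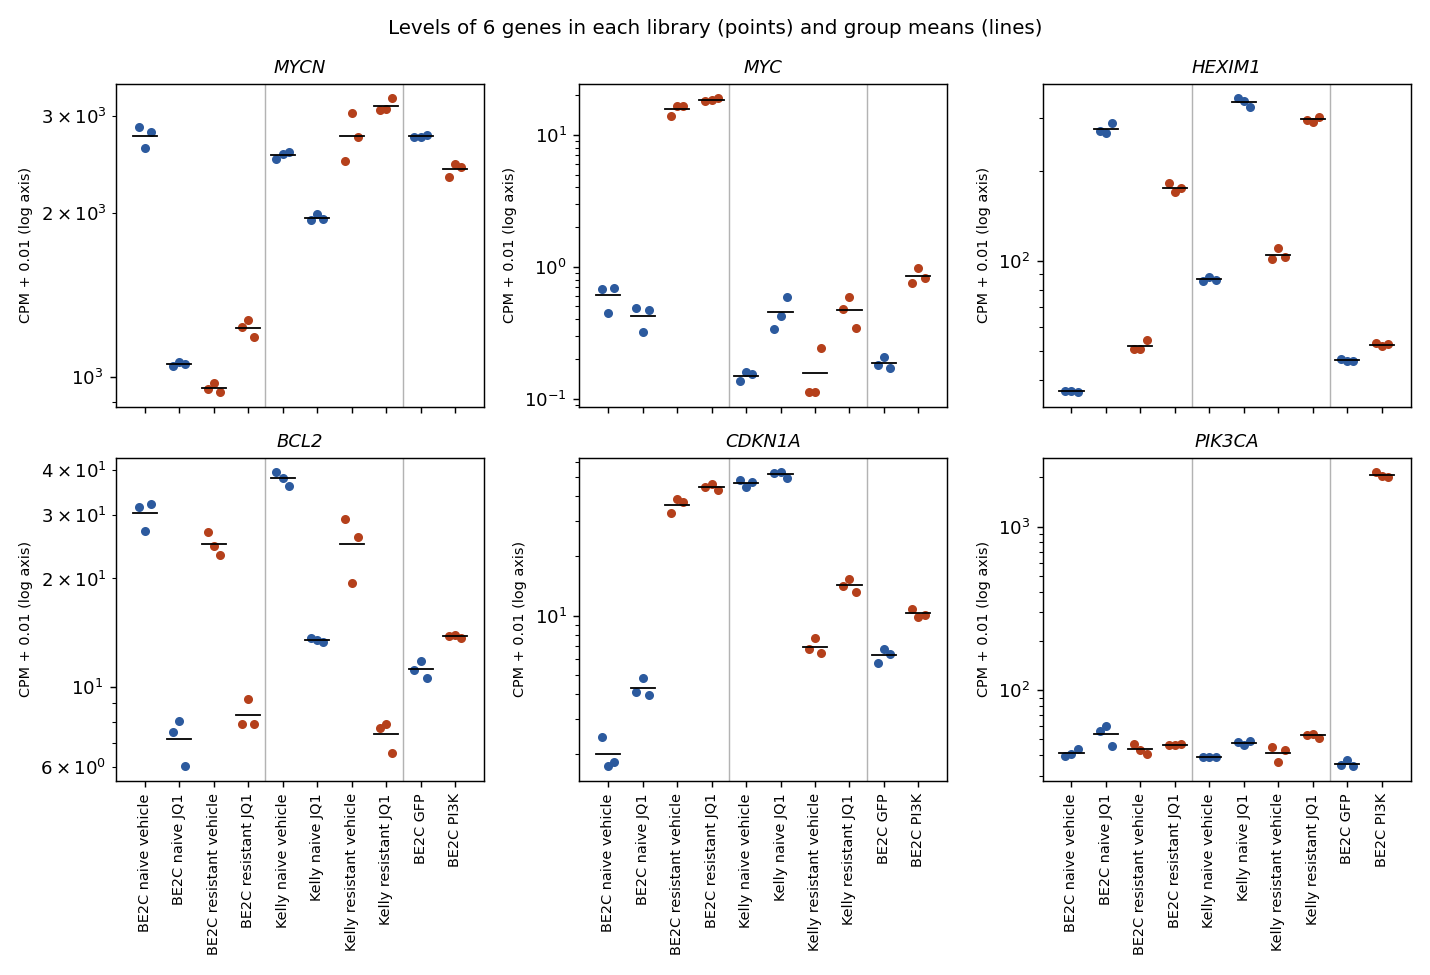
Expression of 6 genes named in advance in the 10 groups, in CPM plus 0.01 on a log axis; points are libraries (orange-red for resistant or PI3K cells, blue for the others) and lines are group means. MYCN was 957 CPM in resistant BE2C vehicle cells against 2765 CPM in naive ones, and PIK3CA was 2070 CPM in PI3K cells against 35.6 CPM in GFP cells.

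Resistant against naive BE2C cells in vehicle asked how the resistant state differed after 24 h in vehicle. MYCN was 957 ± 19.6 CPM in resistant and 2765 ± 128 CPM in naive cells (-1.53 ± 0.05, adjusted p = 2.67e-13), while MYC, its paralog, was 15.7 ± 1.45 against 0.596 CPM (4.71 ± 0.14). CDKN1A was 36.3 ± 3.06 against 1.99 ± 0.381 CPM (4.19 ± 0.12). IL33, an alarmin cytokine, was at least 1187-fold higher (35.3 ± 0.666 CPM against no counts), and SST, the hormone somatostatin, rose by 8.99 ± 0.23 from 0.0692 to 37.5 CPM. The largest fall was that of ARHGAP36, at -10.41 ± 0.26 from 18.5 CPM; the noncoding RNA HOTAIR fell by 6.57 ± 0.15. HEXIM1 was higher by 0.50 ± 0.06 and PIK3CA was at 0.08 ± 0.09 (adjusted p = 0.415). BCL2 was at -0.28 ± 0.10 (adjusted p = 0.0182), a call lost without naive vehicle replicate 1 (-0.25) or 3 (-0.23) or resistant vehicle replicate 3 (-0.24).

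ERK feedback genes, which dampen or report ERK signalling, were higher in 18 of 20 cases with none lower (18 adjusted over the list alone; median 2.16, adjusted p = 2.80e-21). They included the phosphatase DUSP6 (3.44 ± 0.08), SPRY1 (5.50 ± 0.12) and PHLDA1 (4.02 ± 0.08). Mesenchymal state genes were higher in 24 of 29 cases and lower in 2 (24 and 2 adjusted over the list alone; median 2.94, adjusted p = 7.44e-13), among them the adhesion receptor CD44 (3.59 ± 0.06), the Hippo effector YAP1 (4.27 ± 0.11) and SOX9 (3.92 ± 0.12). Fibroblast markers rose with them, in 10 of 11 cases with none lower (10 adjusted over the list alone; median 2.32, adjusted p = 1.24e-09), with the contractile genes ACTA2 (5.40 ± 0.13) and TAGLN (4.21 ± 0.11). These 3 calls held with an estimated correlation. Receptor tyrosine kinases were higher in 19 of 28 cases and lower in 5 (20 and 5 adjusted over the list alone; adjusted p = 8.64e-06, and adjusted p = 0.263 with an estimated correlation), with AXL at 4.39 ± 0.08 and ERBB4 at 5.82 ± 0.19. Neuronal differentiation genes were higher in 18 of 23 and lower in 5 (18 and 5 adjusted over the list alone; adjusted p = 0.000130, and adjusted p = 0.123 with an estimated correlation), with the microtubule protein DCX at 4.82 ± 0.12. G1/S genes were lower in 22 of 28 cases with none higher (22 adjusted over the list alone; median -0.34, adjusted p = 0.00142, and adjusted p = 0.220 with an estimated correlation), and hypoxia and glycolysis genes in 12 of 21 with 2 higher (12 and 2 adjusted over the list alone; adjusted p = 0.0122, and adjusted p = 0.115 with an estimated correlation). Of 23 adrenergic core genes, 13 were lower and 5 higher (14 and 5 adjusted over the list alone; adjusted p = 0.0949), with a median of -0.42 and a mean of 0.18; GATA3 was lower (-2.19 ± 0.09) and DACH1 higher (1.65 ± 0.07). The PI3K pathway components split, 10 higher and 10 lower of 26 (11 and 11 adjusted over the list alone; adjusted p = 0.998). The test called 4878 genes higher and 4824 lower.

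Resistant and naive BE2C cells were also compared in JQ1. There MYCN was slightly higher in resistant cells (0.22 ± 0.05, adjusted p = 0.00136), and MYC was higher by 5.48 ± 0.16. HEXIM1 was lower by -0.65 ± 0.05 and 11 of 12 BET inhibitor marker genes were lower, with 1 higher (11 and 1 adjusted over the list alone; median -1.999, adjusted p = 1.21e-10). GPNMB, a transmembrane glycoprotein, was 54.6 against 0.0783 CPM (9.44 ± 0.24), and NNMT, an enzyme that methylates nicotinamide, was higher by 9.30 ± 0.29. TNRC18 was 1.43 against 42.5 CPM (-4.89 ± 0.17). Mesenchymal, ERK feedback, Wnt and fibroblast lists were higher, in 22 of 29, 19 of 20, 9 of 13 and 10 of 11 cases, with 3, 1, 2 and 0 lower (the same counts adjusted over the list alone). Their medians were 2.85, 2.41, 2.33 and 2.59, at adjusted p = 3.01e-12, 3.44e-24, 1.60e-06 and 3.56e-11. Like the BET markers, they kept their calls with an estimated correlation. MYC family targets were higher in 29 of 35 cases and lower in 2 (29 and 2 adjusted over the list alone; adjusted p = 1.98e-05, and adjusted p = 0.153 with an estimated correlation). The test called 5203 genes higher and 4994 lower.

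JQ1 in naive Kelly cells asked for the response of a second sensitive line. MYCN fell from 2549 ± 34.3 to 1958 ± 26.5 CPM (-0.38 ± 0.06, adjusted p = 4.43e-05). HEXIM1 rose by 1.97 ± 0.05, from 86.9 to 340 CPM, and BCL2 fell by 1.49 ± 0.11. TH, tyrosine hydroxylase, fell from 508 ± 24.5 to 10.4 ± 2.22 CPM (-5.60 ± 0.13). The imprinted gene RTL1 fell by 6.13 ± 0.14 and the amino acid transporter SLC38A5 by 5.77 ± 0.12. The largest rise was that of TBX10, a T-box factor, from 0.147 to 11.7 CPM (6.22 ± 0.17), and ELL2, an elongation factor, rose by 2.54 ± 0.07. CDKN1A was at 0.14 ± 0.07 (adjusted p = 0.0632), and PIK3CA rose by 0.29 ± 0.07.

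All 12 BET inhibitor marker genes rose in naive Kelly cells (12 adjusted over the list alone; median 1.81, adjusted p = 5.43e-17). Catecholamine and secretory granule genes fell in 12 of 20 cases and rose in 6 (12 and 7 adjusted over the list alone; median -0.58, adjusted p = 4.32e-05), including DDC (-3.17 ± 0.06) and DBH (-2.33 ± 0.07). Mesenchymal state genes fell in 17 of 22 cases and rose in 4 (17 and 4 adjusted over the list alone; median -0.94, adjusted p = 0.000544), with CD44 at -3.93 ± 0.14. These 3 calls held with an estimated correlation. G1/S genes, in contrast to BE2C, rose in 19 of 28 cases and fell in 2 (19 and 2 adjusted over the list alone; median 0.29, adjusted p = 0.0122, and adjusted p = 0.294 with an estimated correlation), with CDC6 at 0.58 ± 0.05 and E2F2 at -1.12 ± 0.08; the lines were not tested against each other. Receptor tyrosine kinases fell in 16 cases and rose in 6 (16 and 6 adjusted over the list alone; adjusted p = 0.00718, and adjusted p = 0.294 with an estimated correlation), with TYRO3 at -2.55 ± 0.08. Fibroblast markers fell in 7 of 9 cases and rose in 1 (7 and 1 adjusted over the list alone; adjusted p = 0.00409, and adjusted p = 0.0598 with an estimated correlation). The test called 4787 genes higher and 5338 lower of 15052.

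The response of resistant Kelly cells to JQ1 was compared with that of naive ones in the same way. MYCN had an interaction of 0.56 ± 0.09 (adjusted p = 0.000335) and HEXIM1, which rose by 1.51 ± 0.05, one of -0.46 ± 0.07. MYCN itself was at 0.18 ± 0.06 (adjusted p = 0.0198), a call lost without resistant vehicle replicate 1 (0.12) or resistant JQ1 replicate 3 (0.16). TH fell by 4.97 ± 0.13, from 232 to 7.41 CPM. The immediate-early factors EGR1 and FOS rose by 2.27 ± 0.11 and 2.26 ± 0.09, with interactions of 2.36 ± 0.18 and 1.51 ± 0.14. CDKN1A rose by 1.03 ± 0.08, to 14.2 CPM. All 12 BET inhibitor marker genes rose (12 adjusted over the list alone; median 1.49, adjusted p = 1.20e-18, held with an estimated correlation), and 6 had a negative interaction with none positive (7 adjusted over the list alone; adjusted p = 0.00381, and adjusted p = 0.233 with an estimated correlation).

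Of 28 G1/S genes, 21 had a negative interaction in Kelly and none a positive one (23 adjusted over the list alone; median -0.35, adjusted p = 1.11e-10), with MCM6, a helicase subunit, at -0.45 ± 0.07. G2/M genes went the other way, 13 of 27 positive and none negative (16 adjusted over the list alone; median 0.21, adjusted p = 2.84e-06), with HMMR at 0.61 ± 0.08. Catecholamine genes had 7 positive and 2 negative interactions (8 and 3 adjusted over the list alone; median 0.45, adjusted p = 3.78e-10), with DDC at 2.39 ± 0.07 and the noradrenaline transporter SLC6A2 at 1.79 ± 0.08. ERK feedback genes had 9 positive and 3 negative of 19 (10 and 3 adjusted over the list alone; median 0.24, adjusted p = 4.90e-05), with PHLDA1 at 1.36 ± 0.10. These 4 calls held with an estimated correlation. The test called 3803 genes higher and 4267 lower in resistant cells, and 1395 positive and 1370 negative interactions.

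Resistant against naive Kelly cells in vehicle left MYCN at 0.11 ± 0.06 (adjusted p = 0.123) and MYC at 0.10 ± 0.45 (adjusted p = 0.872). LEF1, a transcription factor of Wnt signalling, was 34.96 ± 0.790 against 0.102 CPM (8.37 ± 0.14), and FGF13 was higher by 6.59 ± 0.14. AGPAT3, an acyltransferase of lipid synthesis, had no counts in resistant cells and was at least 828-fold lower than the 20.5 ± 0.961 CPM of naive cells. ABCB1, the drug efflux pump P-glycoprotein, was 0.0256 against 63.7 ± 0.537 CPM (-11.15 ± 0.22), and the imprinted gene PEG3 fell by 10.73 ± 0.28. CDKN1A was 6.95 against 46.8 CPM (-2.75 ± 0.08). BCL2 fell by 0.60 ± 0.10 and PIK3CA was at 0.09 ± 0.07 (adjusted p = 0.253).

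ERK feedback genes were higher in 12 of 19 cases and lower in 3 in resistant Kelly cells (12 and 3 adjusted over the list alone; median 0.54, adjusted p = 0.000591), led by the ETS factor ETV4 (4.39 ± 0.10) and SPRY4 (3.90 ± 0.10), while CCND1, cyclin D1, was lower (-0.91 ± 0.06). Mesenchymal genes were lower in 15 of 22 cases and higher in 4 (15 and 4 adjusted over the list alone; median -0.82, adjusted p = 0.000260), among them the filament protein VIM (-3.92 ± 0.07) and PRRX1 (-6.43 ± 0.20). The CDK inhibitors and cyclins were lower in 9 of 14 cases and higher in 1 (9 and 1 adjusted over the list alone; median -0.39, adjusted p = 0.00118), including CDKN2A (-5.46 ± 0.14) and CDKN2B (-3.97 ± 0.20), which restrain CDK4 and CDK6. These 3 calls held with an estimated correlation. Other calls did not. MYC family targets were higher in 27 of 35 cases with none lower (27 adjusted over the list alone; adjusted p = 0.00457, and adjusted p = 0.304 with an estimated correlation). Hypoxia and glycolysis genes were lower in 16 of 21 cases and higher in 2 (16 and 2 adjusted over the list alone; adjusted p = 0.000697, and adjusted p = 0.364 with an estimated correlation). The adrenergic list, with INSM1 at -5.26 ± 0.11, was lower in 13 cases and higher in 5 (13 and 5 adjusted over the list alone; adjusted p = 0.0154, and adjusted p = 0.304 with an estimated correlation). Among receptor tyrosine kinases RET was higher (3.45 ± 0.06) and PDGFRA lower (-5.30 ± 0.09), with no call for the list (10 higher, 11 lower of 28, the same adjusted over the list alone; adjusted p = 0.652). Drug efflux genes split, 2 higher and 2 lower of 6 (2 and 2 adjusted over the list alone), with a median of 0.09 and a mean of -2.05. Their call, on the lower side (adjusted p = 0.0473, and adjusted p = 0.352 with an estimated correlation), was lost without resistant vehicle replicate 2 (adjusted p = 0.103). Fibroblast markers gave no call (2 higher, 5 lower of 9, the same adjusted over the list alone; adjusted p = 0.103), and the test called 4532 genes higher and 4594 lower.

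Resistant and naive Kelly cells were also compared in JQ1. LEF1 was higher by 10.05 ± 0.20 and MYCN by 0.68 ± 0.06. TNFRSF10D, a decoy receptor for TRAIL, was at least 746-fold lower than the 24.3 ± 0.550 CPM of naive cells. ERK feedback genes were higher in 15 of 19 cases and lower in 2 (15 and 2 adjusted over the list alone; median 0.96, adjusted p = 1.46e-09), CDK inhibitors and cyclins were lower in 11 of 14 with none higher (12 adjusted over the list alone; median -0.45, adjusted p = 2.89e-05), and neuronal genes were lower in 16 of 24 and higher in 5 (16 and 5 adjusted over the list alone; median -0.48, adjusted p = 0.000464), with STMN4 at -3.06 ± 0.09. These 3 calls held with an estimated correlation. Interferon response genes were higher in 4 of 10 cases with none lower (4 adjusted over the list alone; adjusted p = 0.0150, and adjusted p = 0.234 with an estimated correlation), with OAS3 at 3.44 ± 0.14. The test called 3903 genes higher and 4109 lower.

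PI3K against GFP in BE2C cells asked what forced PI3K expression alone changes. PIK3CA, the catalytic subunit p110 alpha, was 2070 ± 68.9 against 35.6 ± 1.72 CPM (5.86 ± 0.05, adjusted p = 6.86e-21). PIK3CB and PIK3R1 rose by 0.20 ± 0.04 and 0.28 ± 0.04, PIK3CG rose by 1.49 ± 0.38 but stayed under 1 CPM, and PIK3CD was at -0.01 ± 0.29 (adjusted p = 0.972). MYCN fell by 0.20 ± 0.03, from 2757 to 2402 CPM. CDKN1A and BCL2 rose by 0.71 ± 0.07 and 0.30 ± 0.06. APLNR, the apelin receptor, rose by 4.92 ± 0.04, from 6.24 ± 0.149 to 190 ± 2.36 CPM, and LMO2, a haematopoietic transcription cofactor, by 4.55 ± 0.16. BDNF, a neurotrophin, fell by 2.63 ± 0.08.

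ERK feedback genes rose in 19 of 20 cases in PI3K cells with none lower (19 adjusted over the list alone; median 1.13, adjusted p = 1.53e-20, held with an estimated correlation), with PHLDA1 at 2.69 ± 0.05 and DUSP4 at 1.14 ± 0.04. No other list kept its call with an estimated correlation. Adrenergic core genes fell in 13 of 21 cases and rose in 5 (13 and 5 adjusted over the list alone; median -0.53, adjusted p = 1.48e-07, and adjusted p = 0.126 with an estimated correlation), with HAND2 and MEIS2 at -0.88 ± 0.03 and -1.12 ± 0.03. FOXO targets fell in 13 of 24 cases and rose in 3 (13 and 3 adjusted over the list alone; adjusted p = 0.000373, and adjusted p = 0.126 with an estimated correlation), with CCNG2 at -1.25 ± 0.06 and YPEL3 at -1.31 ± 0.06. Mesenchymal genes rose in 13 of 28 and fell in 4 (13 and 4 adjusted over the list alone; adjusted p = 0.00384, and adjusted p = 0.126 with an estimated correlation), with IFI16 at 2.59 ± 0.07. Wnt targets rose in 8 of 14 and fell in 3 (8 and 3 adjusted over the list alone; adjusted p = 0.00240, and adjusted p = 0.202 with an estimated correlation), with BAMBI at 3.16 ± 0.05. Hypoxia genes fell in 16 of 22 and rose in 2 (16 and 2 adjusted over the list alone; adjusted p = 0.000373, and adjusted p = 0.455 with an estimated correlation), with ADM and NDRG1 at -2.23 ± 0.07 and -2.45 ± 0.12. The PI3K pathway components gave no call (8 higher, 10 lower of 29, the same adjusted over the list alone; adjusted p = 0.0592). All 4 tested blood and endothelial markers rose (4 adjusted over the list alone), too few for a list test, with the endothelial cadherin CDH5 at 2.45 ± 0.14. Fibroblast markers rose in 7 of 10 cases and fell in 1 (8 and 1 adjusted over the list alone; adjusted p = 0.0651). No mitochondrially encoded gene was among the genes tested in any comparison. The test called 4414 genes higher and 4319 lower of 15074.

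**Figure D3:**
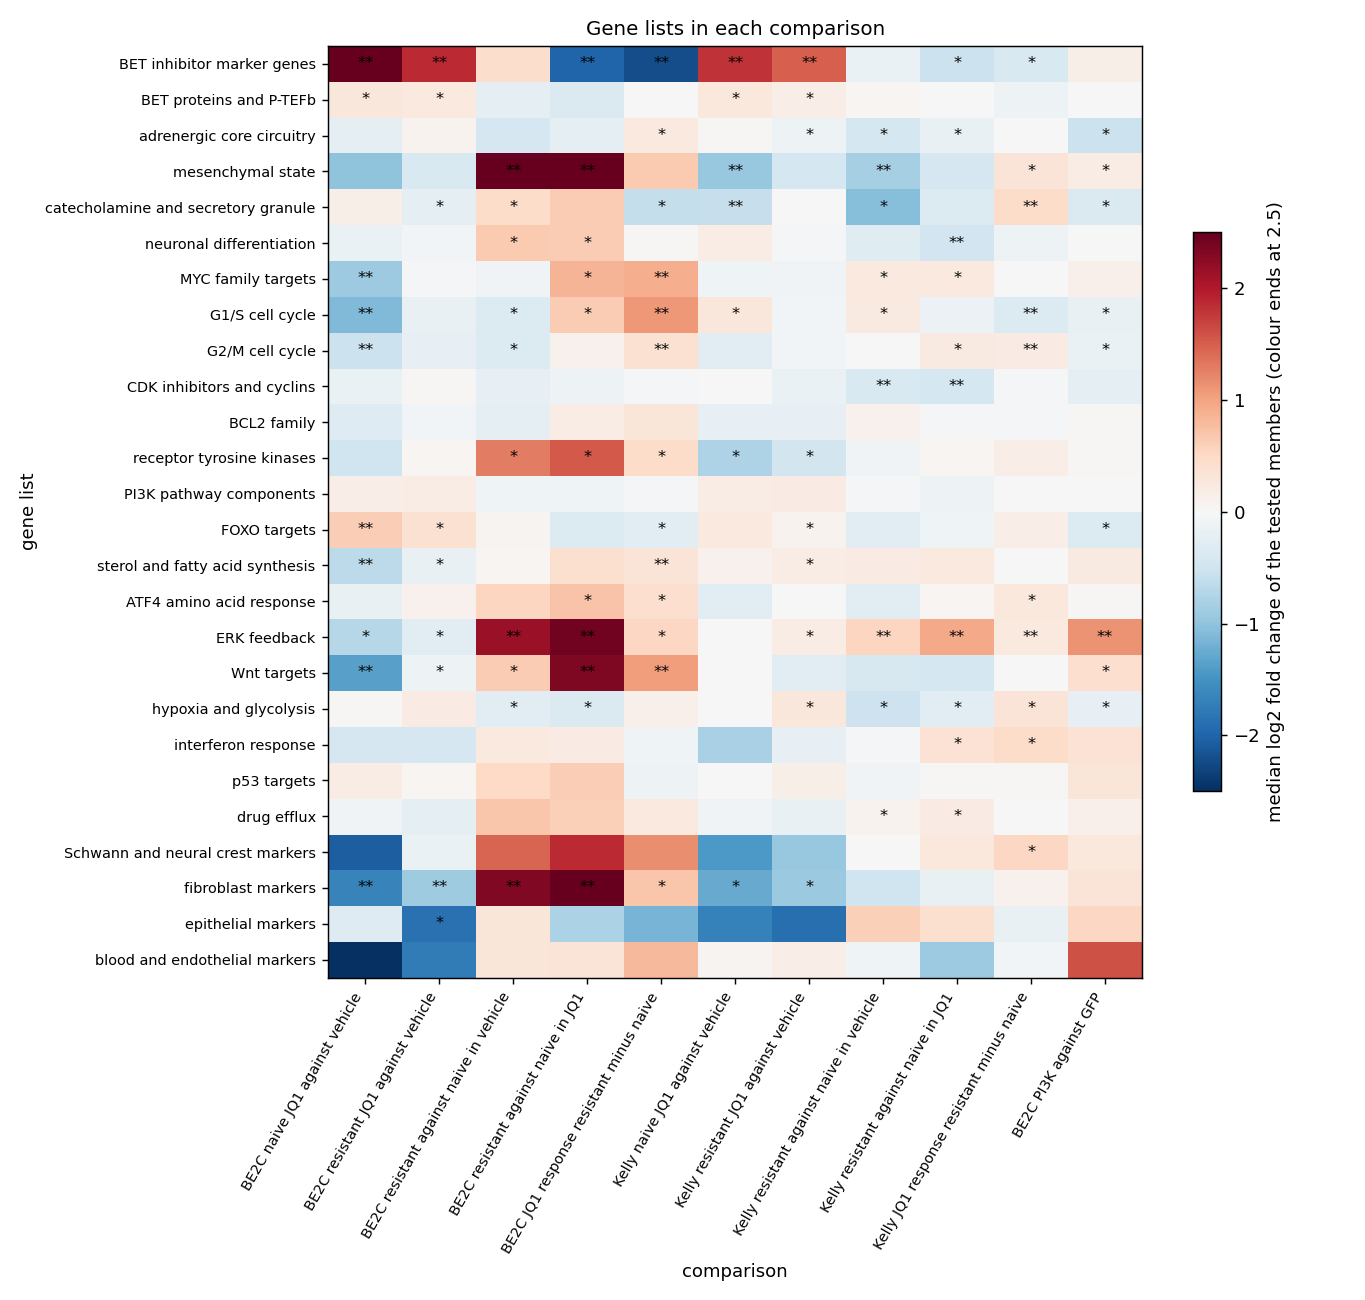
Median log2 fold change of the gene lists (vertical) in the 11 comparisons (horizontal), with the colour scale ending at 2.5; a single star marks a camera adjusted p under 0.05 and a double star a call that also held with an estimated correlation. BET inhibitor marker genes rose in all 4 JQ1 comparisons, with medians of 4.12, 1.87, 1.81 and 1.49.

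**Figure D4:**
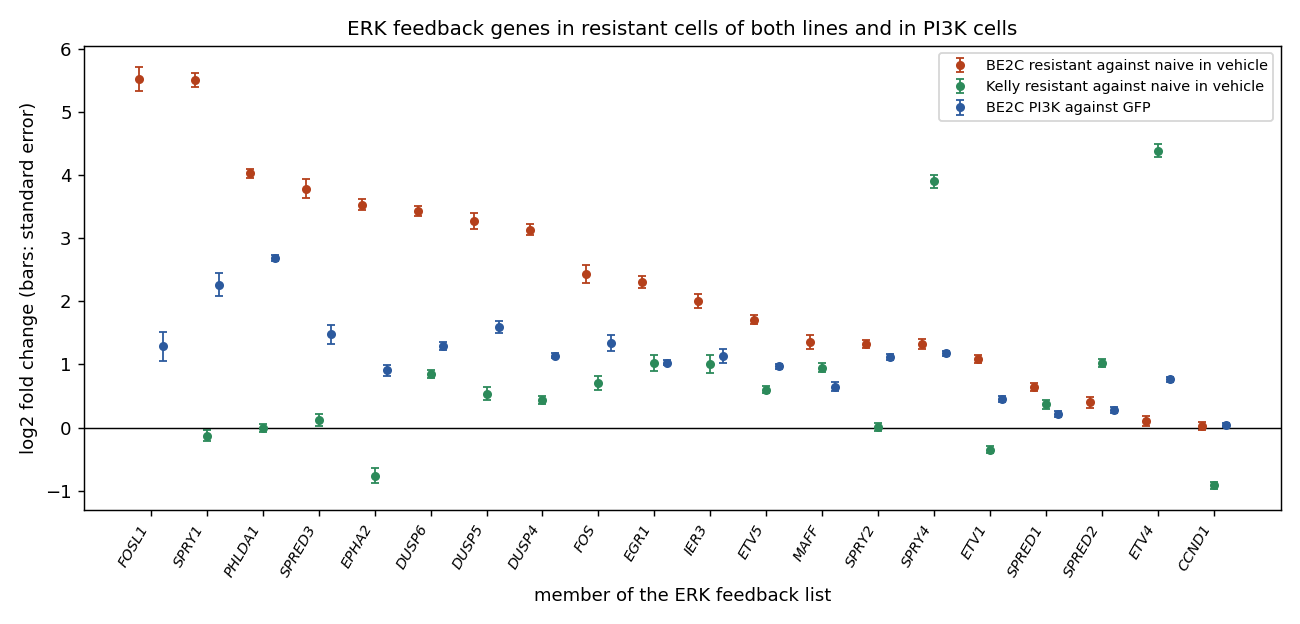
Log2 fold change ± SE of each ERK feedback gene in resistant against naive BE2C cells (red-brown), resistant against naive Kelly cells (green), both in vehicle, and PI3K against GFP BE2C cells (blue). The medians were 2.16, 0.54 and 1.13, and CCND1, 1 of 3 genes lower in Kelly, was at -0.91.

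The JQ1 response was compared between the lines through lists taken from libraries of the other line. Of the 200 strongest BE2C rises, 197 were tested in naive Kelly cells, where 164 rose and 14 fell (median 0.71, adjusted p = 1.70e-30); of 194 falls, 167 fell and 9 rose (median -1.24, adjusted p = 2.72e-51). In resistant Kelly cells the same lists gave 163 higher and 12 lower, and 165 lower and 9 higher. The strongest Kelly rises and falls moved alike in naive BE2C cells, with 162 of 194 higher and 176 of 189 lower. These calls held with an estimated correlation. In the Kelly interaction the BE2C rises had a median of -0.19 (adjusted p = 2.00e-08) and the falls one of 0.22 (adjusted p = 1.27e-11). In the BE2C interaction the Kelly rises had a median of -0.25 and the falls one of 0.67 (adjusted p = 9.23e-08 for each), the latter at adjusted p = 0.118 with an estimated correlation. Across 13849 genes tested in both lines, the naive responses had a Pearson r of 0.592 and a Spearman rho of 0.528; genes are not independent replicates. Of these, 2803 were higher in both lines against 1696 for independent lists, and 2972 lower in both against 1759.

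The resistant states of the lines were compared in the same way. The correlation of resistant against naive changes in vehicle was -0.0156 (rho 0.0840) across the same genes. The strongest BE2C falls, such as ARHGAP36, were lower in Kelly in 127 of 190 cases and higher in 31 (median -0.65, adjusted p = 8.35e-15), and the strongest Kelly rises were higher in BE2C in 97 of 177 cases and lower in 41 (median 0.30, adjusted p = 1.77e-06); both held with an estimated correlation, and both were lost when all called genes were taken in place of the strongest 200 (adjusted p = 0.510 and 0.385). The strongest BE2C rises leaned lower in Kelly, 57 higher and 84 lower of 172 (median -0.16, adjusted p = 0.00690, and adjusted p = 0.255 with an estimated correlation), and with all called genes the direction turned (adjusted p = 0.576). The strongest Kelly falls were at a median of 0.25 in BE2C (adjusted p = 0.220), and passed with the top 100 genes (adjusted p = 0.00334) or without Kelly naive vehicle replicate 2 (adjusted p = 0.0376).

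PI3K expression was compared with resistance in the same way. The strongest BE2C resistance rises rose in PI3K cells in 121 of 187 cases and fell in 19 (median 0.70, adjusted p = 1.12e-28), and the falls fell in 131 of 200 and rose in 32 (median -0.27, adjusted p = 1.88e-16). The strongest Kelly resistance rises rose in 108 of 184 cases and fell in 40 (median 0.22, adjusted p = 7.45e-11). These 3 calls held with an estimated correlation. The Kelly falls fell in 54 of 149 cases and rose in 38 (adjusted p = 0.205), and passed with all called genes (adjusted p = 0.00920). Across genes, the PI3K changes correlated with BE2C resistance at r = 0.411 (rho 0.329, 14268 genes) and with Kelly resistance at r = 0.141 (rho 0.165, 14047 genes), where genes are again not independent replicates. PHLDA1 was higher in PI3K cells (2.69) and resistant BE2C cells (4.02) and at -0.01 ± 0.07 in resistant Kelly cells.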

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

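Tests chosen only after their results were seen were those of MYCN gene copies, of admixture, of fibroblast RNA in both lines and of markers already raised, and the HOX and TRIM29 values below were chosen in the same way. The 8 results below were picked out because the JQ1 response differed between resistant and naive cells of the same line by the interaction test, and they were selected for their biology, after their values were seen, from 7051 such genes in BE2C and 2765 in Kelly and from the list tests. In BE2C the differences on the log2 scale were 1.75 for MYCN, -2.23 for the median BET inhibitor marker gene, 1.08 for the median G1/S gene and 0.914 for the median MYC family target. In Kelly they were 0.565 for MYCN, 0.631 for TH, -0.347 for the median G1/S gene and 0.453 for the median catecholamine and secretory granule gene. The directions for the G1/S list were thus opposite in the 2 lines, a contrast between lines that was not tested. Groups of 3 libraries were not tested for single deviating libraries, but 2 libraries stood apart from their replicates. The chi-squared per degree of freedom between counts was 38.1 and 38.6 for BE2C naive vehicle replicate 2, against 3.40 between the other replicates, and 29.2 and 39.6 for Kelly resistant vehicle replicate 2, against 7.88. Without the first the BE2C interaction had 4000 positive and 4034 negative genes, and without the second the Kelly interaction had 1752 and 1982, each the highest count with 1 replicate left out.

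Chance was examined by regrouping the libraries. For both interactions the real assignment of 12 libraries to 4 groups was the 1 of 50 with as many genes (BE2C 7051 against at most 984 in the others, Kelly 2765 against at most 1378). The random assignments also mixed resistant with naive and JQ1 with vehicle libraries, which widens the spread within groups. They therefore do not test the interaction alone, and chance as a source of its calls was not excluded. For the comparisons of 3 with 3 libraries, 10 splits cannot give a share under 0.05. Fitted on those 6 libraries alone by edgeR, the real splits called 10020 genes (naive JQ1), 8520 (resistant JQ1), 8760 (resistant against naive in vehicle) and 10723 (in JQ1) in BE2C. They called 10920, 6777, 8173 and 8880 in Kelly, in the same order, and 8733 for PI3K. The highest count of any other split was 0 in each of the 9, with at most 194, 200, 638 and 116 genes at an unadjusted p under 0.05 in BE2C, 68, 176, 238 and 329 in Kelly and 256 for PI3K. Each of those other splits put libraries of both groups on each side, which widens the spread within sides. Their counts therefore say little about chance, which was not excluded here either.

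MYCN was lower in resistant than in naive BE2C cells in vehicle (-1.53) and no longer fell with JQ1. The change was -1.55 or below with RLE factors, total counts and DESeq2. These scalings moved genes by a median of only -0.0139, -0.0392 and -0.0142, so the choice among them does not account for it. Being relative, they cannot show a change in total RNA per cell. The interaction of 1.75 (SE 0.07), for which MYCN was flagged, goes against a loss of MYCN gene copies with regulation unchanged. Such a loss would carry the same difference into JQ1. Copy loss together with changed regulation stayed open, and DNA was not measured. Admixture of cells without MYCN expression, with the others regulated as naive ones, would also carry the difference into JQ1. As the whole explanation it is opposed by MYCN being higher, by 0.22 (SE 0.05), in resistant than in naive cells in JQ1. That value comes from the same groups as the interaction and is not separate evidence. The first test for admixture, the median of 25 other adrenergic and catecholamine genes with at least 50 CPM, gave -0.14 with an interval over 10000 resamples of -0.77 to 0.14, which lies above the change of MYCN but crosses the bound of -0.75 set for that test (7 genes higher and 12 lower), so that some admixture stayed open. A resistant state with lower MYCN that is less tied to BET proteins is a hypothesis, and the derivation of the resistant cells, which may have selected for it or for other differences, was not tested. In vehicle their MYCN (957 CPM) was already near that of naive cells in JQ1 (1059 CPM). Whether they had been kept in JQ1 until then is not stated.

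ERK feedback genes were higher in resistant cells of both lines and in PI3K cells. The lowest median over the 3 comparisons and 2 other scalings was 0.47. The choice among these relative scalings therefore does not account for the higher values. The list was tested again by camera without its 4 members of smallest adjusted p, whatever their direction. The remaining 16 genes had medians of 1.53 in resistant BE2C cells and 0.998 in PI3K cells, so a few strong members do not carry it alone there. In Kelly the remaining 15 genes had a median of 0.43 and kept camera p = 0.0298 (p = 0.0489 with an estimated correlation, close to the threshold). Some genes of the list, such as CCND1, were lower in Kelly, and leaving out a lower gene raises the rest. Whether the strongest rises carry the Kelly call was therefore not decided. Fibroblast RNA would bring the abundant fibroblast transcripts COL1A2 and POSTN. These were at 0 CPM in resistant Kelly vehicle cells, where the marker list was divided and COL6A3 was higher (1.51). They were at most at 0.663 CPM in resistant vehicle or PI3K BE2C cells. There, however, COL1A1 rose, and most markers were higher in resistant cells, ACTA2 and TAGLN among them. The pair was picked from the list after the values were seen, and in Kelly it replaced the list median of -0.49. Higher ERK signalling downstream of different receptors or of PI3K is a hypothesis consistent with these values. Signalling itself was not measured, and handling of the cells or growth factors in the medium, which move immediate-early genes such as FOS and EGR1, stayed open.

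BET inhibitor marker genes rose less with JQ1 in resistant than in naive BE2C cells (median interaction -2.23). Histone paralogs that share reads do not explain it alone, since HEXIM1 and SERPINI1, which are not histone genes, had interactions of -1.15 or below. All other members of the list are histone genes. The G1/S list also differed in this contrast (median interaction 1.08), and these differences were not separated. The markers were not simply raised beforehand, as their median between resistant and naive cells in JQ1 was -1.999. Their median interaction was -2.22 or below with RLE factors and with total counts. These relative scalings moved genes by a median of only 0.00507 and -0.00991, so only the choice among them was tested. Values that go against a weaker effect on every gene are those of HOX genes, with a median of -1.06 with JQ1 in resistant and -1.01 in naive cells (median interaction -0.06), and of TRIM29, which fell more in resistant cells (interaction -2.39, SE 0.39). A weaker effect of the drug on some genes, these markers among them, is a hypothesis, and less JQ1 reaching its target could contribute and was not tested.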

How the results depend on the processing

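The list tests with a replicate left out, the other settings for the large changes shared by 3 comparisons and the estimated correlation for gene families were chosen after the data had been seen. All 22 counts of genes higher or lower stayed within 1.5 times the reported count with RLE factors, total counts, DESeq2, no filter, a stricter filter and a replicate block, and with each replicate left out. With total counts the balance shifted, most in the Kelly interaction (1583 positive and 1044 negative, 60.3% positive against 50.5%) and in Kelly resistance in vehicle (3643 higher and 5273 lower, 40.9% higher against 49.7%), as the median of all genes moved by 0.0387 and -0.0644. The 16 counts that could be refitted on 2 groups alone did so too. Leaving out 1 replicate gave 4943 to 5371 genes higher and 5121 to 5531 lower for JQ1 in naive BE2C cells, 4606 to 5300 and 4546 to 5033 for BE2C resistance in vehicle, and 1011 to 1752 and 940 to 1982 for the Kelly interaction. Asking in addition for a log2 change of at least 1 lowered every count by construction. In BE2C it left 1428 higher and 2153 lower (naive JQ1), 340 and 1118 (resistant JQ1), 1936 and 1194 (resistant against naive in vehicle), 2112 and 1295 (in JQ1) and 1091 and 715 (interaction). In Kelly it left 495 and 2092, 303 and 1270, 576 and 1737, 731 and 1395, and 404 and 82 in the same order, and 647 and 362 for PI3K. With a replicate left out, 263 tests between experiments kept their side of the threshold and 1 gained a call. The falls of Kelly resistance in BE2C ranged from adjusted p = 0.0376, without Kelly naive vehicle replicate 2, to 0.511, and passed with the top 100 genes (0.00334). With all called genes the BE2C resistance rises turned direction in Kelly (0.576), the BE2C falls (0.510) and the Kelly rises in BE2C (0.385) lost their calls, and the Kelly falls gained one in PI3K cells (0.00920); the cause was not tested. An estimated correlation ended the calls of the Kelly JQ1 falls in the BE2C interaction (0.118) and of the BE2C resistance rises in Kelly (0.255). Among the gene list tests it ended 68 calls, and 202 kept their side. With fry, which tests the members alone, 118 lists gained a call and 2 turned direction, G2/M genes between resistant and naive BE2C cells in JQ1 (0.00355) and MYC targets in naive Kelly cells in JQ1 (0.0332). Libraries correlated best with their own replicate number in 2 of 12 (BE2C), 2 of 12 (Kelly) and 2 of 6 cases (PI3K), and with a replicate block 1332 of the named-gene results kept their side, 10 lost and 2 gained a call. In DESeq2 1337 kept it and 7 lost it. With 1 replicate left out, 9351 named-gene results kept it, 149 lost and 25 gained a call, and of the gene list tests 1883 kept it, 16 lost and 15 gained one. Depth was not varied, so what it limits was not separated from replicate spread. In simulations with only 200 changed genes, at the depth and spread of each comparison, changes of 0.5 were recovered in as few as 29.9% of cases, in the BE2C interaction.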

Other observations

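The gene families below, their estimated correlation, the other settings for the shared changes and the intervals for neighbouring genes were chosen only after the data had been seen.

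Families grouped by symbol, 11 in each of the 11 comparisons, were tested against all other genes. Values are given as adjusted p, then adjusted p with an estimated correlation. The 3 with any call under both the preset and the estimated correlation are described for the 4 JQ1 responses. Replication-dependent histone genes rose with JQ1 in 44 of 45 cases in naive BE2C cells (median 3.47, adjusted p = 1.46e-36, and adjusted p = 0.00552 with an estimated correlation) and in 32 of 45 in resistant ones (median 1.63, 4.81e-13 and 0.0244). In Kelly they rose in 35 of 47 cases (median 1.18, 2.21e-10 and 0.0213) and in 32 of 47 (median 0.78, 6.67e-09 and 0.00537). They were lower in resistant than in naive BE2C cells in JQ1 in 44 of 45 cases (median -2.26, 3.73e-17 and 0.0433), with 34 negative interactions (median -2.08, 2.22e-15 and 0.0375). In Kelly the same comparison had 26 of 47 lower (median -0.50, 0.128 and 0.592) and 8 of 47 negative interactions (median -0.30, 0.0124 and 0.223). Histone paralogs share sequence, so counts of single members are uncertain. This family includes the histone members of the BET inhibitor marker list, so it is not separate evidence from that list. HOX genes fell in 13 of 15 cases in naive BE2C cells (median -1.01, 0.00188 and 0.241), 12 of 15 in resistant BE2C cells (-1.06, 4.82e-08 and 0.0244), 11 of 15 in naive Kelly cells (-1.28, 2.93e-06 and 0.0469) and 11 of 15 in resistant Kelly cells (-0.83, 2.17e-05 and 0.0682). Collagens fell in 17 of 30 (-1.37, 0.0137 and 0.327), 20 of 30 (-0.94, 1.84e-08 and 0.0266), 22 of 28 (-1.75, 1.30e-08 and 0.0344) and 19 of 28 cases (-1.10, 8.82e-06 and 0.0264) in the same order. Calls of the other 8 families were lost with an estimated correlation, among them those of ribosomal protein genes in naive BE2C cells in JQ1 (70 of 78 higher, 0.000234 and 0.751) and of potassium channels in naive Kelly cells in JQ1 (43 of 63 lower, 5.96e-05 and 0.125). These medians kept their direction with RLE factors and with total counts.

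Genes with a log2 change of at least 1 in the same direction in resistant BE2C cells, resistant Kelly cells and PI3K cells numbered 46 higher and 60 lower of 13664, against 1.22 and 1.83 for independent lists. Counts were 42 to 53 and 60 to 71 with other scalings, DESeq2, no filter or a replicate block, and 11 and 14 with a stricter filter, which tests fewer genes. Among the higher genes, in that order, were LMO2 (5.07, 4.25 and 4.55), the Wnt target BAMBI (2.61, 2.78 and 3.16) and SPRY4 (1.32, 3.90 and 1.18). Among the lower ones were ARHGAP36 (-10.41, -6.49 and -2.42), SERPINF1 (-3.07, -3.22 and -2.84), MEIS2 (-1.60, -1.28 and -1.12) and the cell cycle kinase CDK6 (-2.02, -1.11 and -1.03). These genes were chosen after their values were seen. Genes prone to large changes in any direction could give such a number. The agreeing combinations held 37.7 and 32.8 times the independent count, however, and the disagreeing ones 3.91 to 18.8 times, the highest being 65 genes higher in BE2C and PI3K cells and lower in Kelly, so that proneness was not enough to account for it. The remaining hypothesis, a change shared by resistance and PI3K expression, may include effects of growing cells under selection, which the design does not separate. GFP cells were engineered too, which matches delivery of a transgene as such, though not other differences between the GFP and PI3K derivations.

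Changes shared along chromosomes, as gained or lost segments would give, were tested as the correlation across genes of each log2 fold change with the median of its 20 nearest tested neighbours. At least 94.3% of the genes could be placed by symbol. The correlation was 0.207 in resistant BE2C cells in vehicle and 0.242 in JQ1, and 0.233 and 0.246 in resistant Kelly cells, against 0.142 and 0.111 for JQ1 in naive cells of the 2 lines, and 0.165 for PI3K; the highest of 100 shuffled orders in any comparison was 0.0302. The margin over the JQ1 response had been set at 0.1. The difference was 0.0653 in BE2C in vehicle (interval over 1000 resamples of the chromosomes -0.0319 to 0.155) and 0.1002 in JQ1 (0.0290 to 0.173), and 0.122 (0.0446 to 0.192) and 0.135 (0.0620 to 0.203) in Kelly. All 4 intervals held the margin, so whether gained or lost segments are behind part of the differences stayed open in both lines. Genes are not independent replicates, and DNA was not measured.

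AGPAT3 had no counts in resistant Kelly vehicle cells. A deletion reaching the adjacent genes would lower them, but the 4 nearest tested genes had a median log2 fold change of 0.0895, with CSTB at 0.04, RRP1 at 0.14, TRAPPC10 at -0.04 and PWP2 at 0.33. A loss within the gene or silencing was not tested.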
